A study of Mus musculus with 6 samples.

How the data were processed

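RNA-seq libraries of mouse haematopoietic stem cells were compared between 3 freshly isolated samples and 3 samples cultured for 18 h. Per the labels' protocols, RNA was extracted with an RNeasy Plus Micro kit and libraries were made with Smart-seq2, a full-length cDNA method for small cell numbers that amplifies by PCR. Per the submitters' processing notes, Bowtie 1.0.0, TopHat and HTSeq were used with the mouse builds GRCm38 and mm10. Their settings and the gene annotation are not given in the sources used here. The labels also name a drug treatment and its solvent for the series. They do not say whether the cultured cells here received the solvent, and no library of drug-treated or Hsf1-deficient cells is in the samples used here.

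The deposited table holds counts, whole numbers of reads per gene symbol that the authors did not normalise, as seen from the values: totals differ between libraries. It lists 15828 genes, each with at least 1 count in total, so genes with no count in any library are not listed. No row lacks a gene name and no mitochondrially encoded gene is listed. The totals of the fresh libraries 7, 8 and 9 were 12948002, 16698453 and 23387054 counts, and those of the cultured libraries 10, 11 and 12 were 24924061, 22456809 and 23779337. Every column name carries the library number of the sample's title. No pair of libraries in a group held identical values, and chi-square per gene between replicates was 20.2 to 44.2, far above sampling noise, so all 6 were kept as separate samples.

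Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr at default settings, TMM factors, robust quasi-likelihood fit, two-sided F-test, Benjamini-Hochberg adjustment, threshold 0.05), which left 12465 genes. The SE of a log2 fold change was taken as its size divided by the square root of F. TMM factors were 1.107, 1.102 and 1.112 for the fresh and 0.901, 0.912 and 0.897 for the cultured libraries. The common dispersion was 0.0983, a biological coefficient of variation of 0.314. Changes beyond 2-fold were tested with glmTreat on the same fit. CPM values are scaled by the TMM factors. Pearson correlations of log2 CPM (prior count 2) across genes were 0.936 to 0.944 within the fresh, 0.955 to 0.966 within the cultured and 0.874 to 0.893 between the groups. The first principal component held 56.5% of the variance and separated the groups, and the second, 13.2%, set fresh library 9 and cultured library 12 apart from the others of their group.

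There were 33 gene lists with 699 members, of which 675 are in the table, some under an older symbol. They cover chaperones, degradation, ribosomes and translation, the cell cycle, stem cell regulators, signalling, stress, metabolism and the markers of other marrow cells, and some genes stand in more than one list. Lists were tested with camera from limma 3.58.1, again with a correlation estimated per list, and with fry, which tests whether the genes of a list move on balance in the same direction without comparing them to other genes. Members that rose or fell were counted by the edgeR test adjusted over all genes and adjusted over the list alone. Library composition was compared with a two-sided exact permutation test, which cannot give a p below 0.1 for 3 against 3.

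The genes named in the text follow a rule. It takes the 12 largest rises and 12 largest falls that passed the test, did not overlap between the groups, had a mean of at least 32 CPM and were not predicted genes, clones or pseudogenes. It adds, for each list with at least 5 tested members, the 3 members with the smallest p and the largest called member against the majority, and 18 genes named whatever their values (Hsf1, 8 heat shock and co-chaperone genes, Myc, Mki67, Cdkn1c and 6 stem cell genes). Some list members were left out for length, and genes named outside the rule are marked. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

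Coordinates, GC content and transcript length came from GENCODE release M21 on GRCm38. By symbol 14268 genes matched, and 1355 more through a RefSeq synonym, so that 98.4% had a length. The test script was tested on simulated data drawn from the means, dispersions and library sizes of this comparison (12206 genes). It recovered 22.4% of the genes changed 1.5-fold, 46.3% of those changed 2-fold and 83.3% of those changed 4-fold, with 5 false calls among 117 (DESeq2 made 164 calls and limma-voom 116), called the heat shock list when its genes were changed 1.5-fold and called 0 of 32 unchanged lists. A change of 1.5-fold was therefore often missed in the simulation. Few simulated genes were changed, so the adjusted threshold was stricter there than in the real comparison, where far more genes were called. The recovered shares therefore need not hold for the real comparison. The simulated genes were independent, so the list result does not cover correlated genes.

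The alternatives were DESeq2 size factors, total count scaling, upper-quartile factors, no filter on low counts, a filter of at least 50 counts in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, ribosomal protein genes left out, and each library left out in turn. Offsets for GC content and length, and thinning of the libraries to 12948002 counts, were added after the data were seen. Bounds for genes with no count in a group were computed against 3 counts per library. In addition, 6 gene lists were chosen after values were seen and are given only in the closing observations. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Taking out ribosomal protein genes removed 85 genes.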

Results

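Gene expression was measured by RNA-seq in mouse haematopoietic stem cells (HSCs), the rare bone marrow cells that renew themselves and give rise to all blood lineages. The cells came from young adult C57BL6 mice. There were 3 libraries of freshly isolated cells, numbered 7, 8 and 9, and 3 libraries of cells kept in culture for 18 h, numbered 10, 11 and 12. The culture medium contained SCF and TPO, cytokines that sustain HSCs. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical. The fresh libraries held 12948002, 16698453 and 23387054 gene counts and the cultured libraries 24924061, 22456809 and 23779337. At these depths 3 counts, used below as the detection floor, correspond to between 0.115 and 0.210 CPM, the unit of counts scaled to a common library total by TMM, a limit that covers counting error only.

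The design asks how culture alters gene expression in HSCs. The series title names Hsf1, the transcription factor that induces heat shock genes, and proteostasis, the upkeep of the protein pool. After 18 h in culture, the cyclin-dependent kinase inhibitor Cdkn1a had risen from 6.32 ± 2.10 to 314 ± 67.5 CPM (SD, n = 3 libraries per group). All 31 tested proteasome genes rose, as did 26 of 28 genes for ribosome biogenesis, 27 of 29 for DNA replication and 19 of 21 for cholesterol synthesis, while 21 of 36 stem cell genes and 18 of 25 interferon-stimulated genes fell. Of these lists only the proteasome kept its call in a list test with an estimated correlation (adjusted p = 0.036, against 0.0548, 0.220, 0.0881, 0.0881 and 0.189). Hsf1 itself changed by a log2 fold change of 0.33 ± 0.18 (SE), which did not pass the test. Of 12465 genes tested, 2546 rose and 2143 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, two-sided). For 6424 genes, or 51.5%, the libraries of both groups did not overlap, against 10% expected by chance for 3 against 3. All log2 fold changes below are cultured over fresh, with the SE of the fit, and every gene said to have risen or fallen passed the edgeR test, without overlap between the libraries of the groups where the gene is named.

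The split between rises and falls depended on the scaling of the libraries. With TMM factors 54.3% of the called genes were higher in culture. Scaling to total counts moved the median of all genes by -0.29 on the log2 scale, and 1620 genes then rose and 3621 fell, a share of 30.9% higher. Upper-quartile factors moved the median by -0.15 and gave 2063 rises and 2869 falls, a share of 41.8%. The changes given here are relative to the TMM scale. Beyond 2-fold (edgeR test against a minimum fold), 313 genes rose and 268 fell, and limma-voom gave 150 and 101. Total count scaling gave 168 rises and 547 falls beyond 2-fold, and upper-quartile factors gave 208 rises. Without fresh library 7, 8 or 9 the falls beyond 2-fold numbered 173, 170 and 170, and without cultured library 10 there were 174 rises and 171 falls. Without cultured library 11 the rises numbered 190.

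The 12 largest rises among genes with a mean of at least 32 CPM were led by Cdkn1a, with a log2 fold change of 5.63 ± 0.26. S100a4, a calcium-binding protein, followed at 4.75 ± 0.19, Id1, an inhibitor of DNA-binding transcription factors, at 4.45 ± 0.35 and Mthfd2, a mitochondrial enzyme of folate metabolism, at 4.40 ± 0.27. The lysosomal membrane protein gene Cd68 rose by 4.31 ± 0.30 and the tetraspanin gene Cd53 by 4.03 ± 0.21. The beta-tubulin gene Tubb6 (4.03 ± 0.22), Ctla2a (3.93 ± 0.18), the cell cycle transcription factor gene Mybl2 (3.72 ± 0.39), Emilin2 (3.72 ± 0.45), the collagen gene Col18a1 (3.64 ± 0.19) and Afp, which encodes alpha-fetoprotein (3.58 ± 0.21), completed the group. Ctla2a reached the highest level of these, 2751 ± 386 CPM in cultured against 180.2 ± 43.5 CPM in fresh cells. Ctla2a has a close paralog, and its counts are uncertain to the extent that reads were shared. In GRCm38, Cdkn1a lies on chromosome 17 from 29090976 to 29100727, S100a4 on chromosome 3 from 90603771 to 90606045 and Cd68 on chromosome 11 from 69664213 to 69666153.

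The 12 largest falls were led by Lyz2, a lysozyme gene of myeloid cells, which went from 589 ± 39.1 to 38.7 ± 9.50 CPM, a log2 fold change of -3.93 ± 0.18. Lyz2 lies on chromosome 10 from 117277331 to 117282321, beside its near-identical paralog Lyz1, so the counts of both are uncertain. The proteoglycan gene Bgn (-3.47 ± 0.26), Mamdc2 (-3.38 ± 0.49), Cpxm1 (-3.19 ± 0.29) and Ltb, which encodes lymphotoxin beta (-3.14 ± 0.15), came next. Pik3ip1, an inhibitor of phosphoinositide 3-kinase, fell by 2.93 on the log2 scale and the interferon-induced gene Ifi44 by 2.89. The muscle glycogen phosphorylase gene Pygm (-2.83 ± 0.21), Abcg3 (-2.70 ± 0.25), the apolipoprotein gene Apoe (-2.70 ± 0.10), Mob3c (-2.61 ± 0.36) and the adhesion receptor gene Gpr133 (-2.52 ± 0.20) followed. Apoe had the highest fresh level of these genes, 1073 ± 42.3 CPM against 165 ± 12.8 CPM in culture.

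**Figure D1:**
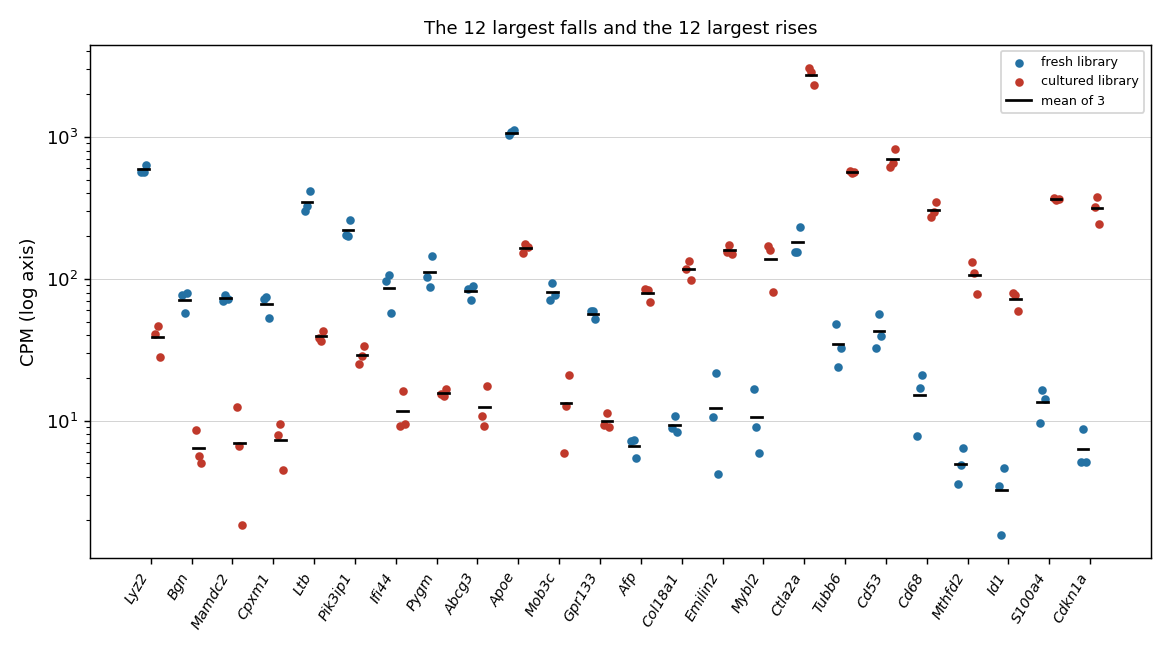
CPM of each library on a log axis for the 12 genes with the largest falls (left, Lyz2 to Gpr133) and the 12 with the largest rises (right, Afp to Cdkn1a), with fresh libraries in blue, cultured libraries in red and a bar at the mean of 3. No fresh library of a gene overlaps a cultured one, which the choice of these genes required, and Cdkn1a goes from a mean of 6.32 to 314 CPM.

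Gene lists fixed before the data were examined were compared with all other genes by camera (limma, preset correlation of 0.01, two-sided, adjusted over 33 lists), which called 24. With a correlation estimated for each list, only the proteasome, translation factor and glycolysis lists kept an adjusted p under 0.05. For each other called list that p is given beside it.

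Cytosolic chaperone genes rose more often than they fell. Of 24 tested heat shock genes and co-chaperones, 12 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.545 and an adjusted p of 0.00184 by camera (adjusted p = 0.189 with an estimated correlation). With total count scaling 5 rose and 3 fell and the median was 0.25. The abundant constitutive chaperone gene Hspa8 went from 3586 ± 68.6 to 6479.7 ± 825 CPM, a log2 fold change of 0.85 ± 0.10. Hspa4 rose by 1.36 ± 0.13, Hsp90ab1 by 0.71 ± 0.10 and Hsp90aa1 by 0.56 ± 0.12, though Hsp90aa1 did not pass with total count scaling (0.27, edgeR adjusted p = 0.0876, the highest of 16 alternatives). The member that fell was the co-chaperone gene Dnajb4 (-1.13 ± 0.28). The genes Dnajb1, Bag3 and Hsph1, named whatever their values, did not pass the edgeR test. Dnajb1 stood at -0.13 ± 0.14 (adjusted p = 0.481), and it was lower with total count scaling (-0.42, adjusted p = 0.0306, the lowest of 16 alternatives that ranged to 0.964). Bag3 stood at 0.45 ± 0.20 (adjusted p = 0.101), or 0.63 without fresh library 8 (adjusted p = 0.0467, in a range of 0.0467 to 0.548 over the alternatives). Hsph1 stood at 0.60 ± 0.22 (adjusted p = 0.0513), and it passed under 8 of 16 alternatives (adjusted p from 0.0142 to 0.286). Hsf1, on chromosome 15 from 76477422 to 76501913, was at 48.2 ± 8.83 CPM in fresh and 60.6 ± 7.66 CPM in cultured cells (edgeR adjusted p = 0.183). The classic inducible gene Hspa1a had 0, 0 and 4 counts in the fresh and 3, 2 and 0 in the cultured libraries and was not tested, and Hspa1b is not listed in the table. Hspa1a and Hspa1b are near-identical copies, so reads from both may have been discarded or shared, and these low counts are uncertain.

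Chaperone genes of other compartments and pathways also rose more often than they fell. Of 14 subunits of the chaperonin TRiC and of prefoldin, 11 rose and 1 fell, also when adjusted over the list alone (median 0.90, camera adjusted p = 4.0e-06, adjusted p = 0.0881 with an estimated correlation), with Tcp1 at 1.22 ± 0.10 and Cct5 at 1.07 ± 0.09. Of 15 mitochondrial chaperones and proteases 10 rose and none fell (12 rose adjusted over the list alone), with a median of 0.58 and a camera adjusted p of 7.0e-05 (adjusted p = 0.0898 with an estimated correlation). With total count scaling 7 rose and 2 fell, with a median of 0.29. Hspe1 rose by 1.51 ± 0.13, Hspa9 by 1.10 ± 0.09 and Hspd1 by 0.98 ± 0.09. In the endoplasmic reticulum, 15 of 22 chaperone and degradation genes rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.52 and a camera adjusted p of 5.1e-05 (adjusted p = 0.323 with an estimated correlation), but 6 rose and 3 fell with total count scaling (median 0.23). The transcription factor gene Xbp1 rose from 363 ± 19.9 to 1201 ± 126 CPM, Sdf2l1 rose by 1.61 ± 0.19 and Dnajb11 by 1.27 ± 0.12.

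Degradation genes split by pathway. All 31 tested subunits of the 26S proteasome, the cell's main protease for ubiquitinated proteins, rose, also when adjusted over the list alone (median 0.99, camera adjusted p = 1.3e-22, adjusted p = 0.036 with an estimated correlation), with Psmb3 at 1.29 ± 0.10, Psmd14 at 1.24 ± 0.10 and Psma3 at 1.06 ± 0.09. With total count scaling 28 of the 31 passed. Among 27 autophagy and lysosome genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 0.0126 (adjusted p = 0.122 with an estimated correlation). The median was -0.52 with total count scaling, -0.39 with upper-quartile factors and -0.15 without fresh library 9. Ulk1, a kinase that starts autophagy, fell by 1.43 on the log2 scale, Map1lc3b, which encodes an autophagosome protein, by 1.31 and the mitophagy receptor gene Bnip3l by 0.72. Atg3 rose by 0.50 ± 0.12, but did not pass with total count scaling (0.21, edgeR adjusted p = 0.178, the highest of 16 alternatives).

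**Figure D2:**
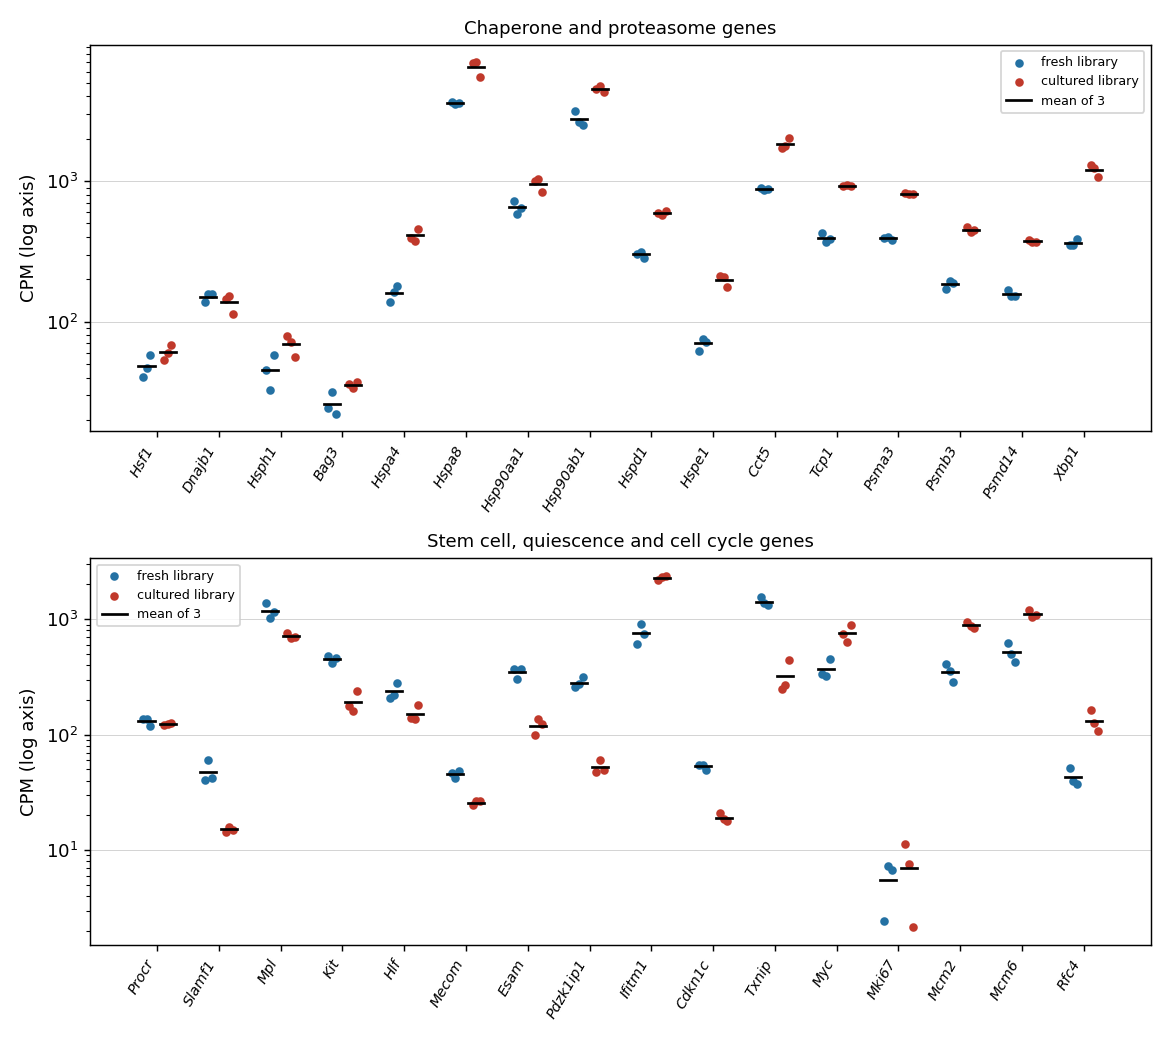
CPM of each library on a log axis for chaperone and proteasome genes (top) and for stem cell, quiescence and cell cycle genes (bottom), with fresh libraries in blue, cultured libraries in red and a bar at the mean of 3. Hsf1, Dnajb1, Hsph1, Procr and Mki67 overlap between the groups, while Psma3 goes from a mean of 391 to 814 CPM and Slamf1 from 47.6 to 15.1 CPM.

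Most genes tested for ribosome biogenesis, tRNA charging and translation rose. Of 28 nucleolar ribosome biogenesis genes, 26 rose and none fell, also when adjusted over the list alone (median 1.21, camera adjusted p = 4.8e-20, adjusted p = 0.0548 with an estimated correlation), with Nhp2 at 1.76 ± 0.11, Bop1 at 1.52 ± 0.12 and nucleolin (Ncl) at 1.17 ± 0.09. Of 20 cytosolic aminoacyl-tRNA synthetases, 19 rose and none fell, also when adjusted over the list alone (median 0.94, camera adjusted p = 4.3e-12, adjusted p = 0.124 with an estimated correlation), with Mars at 1.58 ± 0.13 and Gars at 1.33 ± 0.11. Of 21 translation initiation and elongation factors 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.78 and a camera adjusted p of 1.7e-09 (adjusted p = 0.036 with an estimated correlation). With total count scaling the median of these factors was 0.48. Eif6 rose by 1.51 ± 0.11 and Eif3b by 1.30 ± 0.10. Myc, a transcription factor that drives growth genes, rose from 370 ± 72.0 to 754 ± 125 CPM, a log2 fold change of 1.03 ± 0.16. Genes for ribosomal proteins moved little. Of 31, 14 rose and 1 fell, also when adjusted over the list alone, and the median was 0.20 but -0.09 with total count scaling, 0.05 with upper-quartile factors, 0.13 without fresh library 7 and 0.31 without fresh library 9. The list was called by camera (adjusted p = 0.0397) but not in 8 of 17 alternatives, with a range of 0.00466 to 0.621. Among these 8 were adjusted p = 0.621 with an estimated correlation, 0.305 without fresh library 7 and 0.061 without cultured library 11. They also include fry (adjusted p = 0.0833), which does not compare the list with other genes.

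Most DNA replication genes rose. Of 29 G1/S and replication genes, 27 rose and none fell, also when adjusted over the list alone (median 1.33, camera adjusted p = 9.2e-13, adjusted p = 0.220 with an estimated correlation). Rfc4, a subunit of the clamp loader, rose by 1.63 ± 0.19 and the helicase gene Mcm2 by 1.34 ± 0.13. Of 25 G2/M genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.82 and a camera adjusted p of 0.0214 (adjusted p = 0.621 with an estimated correlation), and with total count scaling 6 rose (median 0.53). Aurkb rose by 2.96 ± 0.61, Bub1 by 2.57 ± 0.53 and Cdk1 by 1.66 ± 0.28, while cyclin B2 (Ccnb2) fell by 1.34 on the log2 scale. The proliferation marker Mki67 stood at 5.49 ± 2.65 CPM in fresh and 7.03 ± 4.61 CPM in cultured cells (edgeR adjusted p = 0.683). Without cultured library 10, 4 G2/M genes rose, the camera adjusted p was 0.0762 (range over the alternatives 8.5e-05 to 0.621) and Mki67 stood at -0.17. Among 19 quiescence-associated regulators, 7 fell and 4 rose (9 and 4 adjusted over the list alone), and the list was not called (median -0.54, camera adjusted p = 0.271). Cdkn1c, a cell cycle inhibitor abundant in resting HSCs, fell by 1.48 on the log2 scale and Txnip by 2.15, whereas Cdkn1a rose.

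Stem cell markers and regulators fell more often than they rose. Of 36, 21 fell and 4 rose, also when adjusted over the list alone (median -0.73, camera adjusted p = 1.7e-05, adjusted p = 0.0881 with an estimated correlation). Pdzk1ip1 fell from 283 ± 29.3 to 52.5 ± 7.38 CPM and the adhesion molecule gene Esam from 349 ± 37.1 to 119 ± 18.5 CPM. Slamf1, which encodes the surface marker CD150, had a log2 fold change of -1.66 ± 0.22, and the SCF receptor gene Kit one of -1.23 ± 0.15. The transcription factor gene Mecom stood at -0.83 ± 0.17, the TPO receptor gene Mpl at -0.73 ± 0.12 and Hlf at -0.64 ± 0.15, all of which passed. Procr, a surface marker of HSCs, did not pass (-0.08 ± 0.12, edgeR adjusted p = 0.647), although it was lower with total count scaling (-0.37, adjusted p = 0.0252, the lowest of 16 alternatives that ranged to 0.892). Ifitm1 rose by 1.60 ± 0.14, and the other members that rose, named after their values were seen, were Ifitm3, Ly6a and Gfi1.

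Targets of cytokine signalling changed in both directions. Of 15 STAT5 targets 7 rose and 4 fell, also when adjusted over the list alone, with a median of 0.34 and a camera adjusted p of 0.0241 (adjusted p = 0.139 with an estimated correlation, 0.0773 by limma-voom). The lowest adjusted p of the alternatives, 0.00029, came from fry, which does not compare the list with other genes. The median was 0.04 with total count scaling, 0.19 with upper-quartile factors and 0.52 without cultured library 12. The feedback inhibitors Cish and Socs2 rose by 1.78 ± 0.12 and 0.92 ± 0.13, and the transcriptional repressor gene Bcl6 fell by 2.80 on the log2 scale. The list does not separate genes that STAT5 raises from genes it lowers, and it holds Stat5a and Stat5b themselves. The counts by direction therefore do not measure STAT5 activity. Of 16 immediate early genes 2 rose and 2 fell, also when adjusted over the list alone, and the list was not called (median 0.10 but -0.19 with total count scaling and -0.05 with upper-quartile factors, camera adjusted p = 0.592). Fosl1 rose from 0.24 ± 0.03 to 15.5 ± 1.48 CPM, and the phosphatase genes Dusp1 and Dusp2 fell by 1.43 and 0.85 on the log2 scale. Of 13 MAPK feedback genes 2 rose, Dusp5 (1.30 ± 0.22) and Egr1 (0.84 ± 0.19), and 1 fell (2 and 0 adjusted over the list alone). The median of this list was -0.09 while its mean of 0.33 and the direction of the camera test were upward (adjusted p = 0.647).

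Genes of the ATF4, p53 and NRF2 stress lists rose more often than they fell. Of 19 genes of ATF4 and the integrated stress response, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.10 and a camera adjusted p of 5.8e-08 (adjusted p = 0.0548 with an estimated correlation). The members that rose most clearly act in amino acid and folate metabolism, with Mthfd2 at 4.40 ± 0.27, the asparagine synthetase gene Asns at 2.22 ± 0.13 and Shmt2 at 1.74 ± 0.12. Of 20 p53 targets 10 rose and 2 fell, also when adjusted over the list alone (median 0.66, or 0.37 with total count scaling, camera adjusted p = 0.00013, adjusted p = 0.196 with an estimated correlation). Besides Cdkn1a, Phlda3 rose by 3.44 ± 0.30 and the apoptosis gene Bax by 2.65 ± 0.16, while Sesn1 fell by 1.58 on the log2 scale. Of 18 NRF2 oxidative stress genes 14 rose and none fell (15 adjusted over the list alone), with a median of 1.14 and a camera adjusted p of 8.4e-14 (adjusted p = 0.0881 with an estimated correlation). The quinone reductase gene Nqo1 rose by 3.42 ± 0.21 and the ferritin light chain gene Ftl1 by 1.62 ± 0.08, to 8041 ± 417 CPM.

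Most of the listed interferon-stimulated genes fell, whereas most inflammatory genes did not pass. Of 25 interferon-stimulated genes, 18 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -1.05 and a camera adjusted p of 6.7e-07 (adjusted p = 0.189 with an estimated correlation). Ifi44 fell from 86.7 ± 25.8 to 11.7 ± 3.98 CPM and the transcription factor gene Irf1 from 252 ± 31.4 to 122 ± 7.60 CPM. Oasl2 had a log2 fold change of -1.20 ± 0.14, and Bst2 was the member of this list that rose (0.84 ± 0.16). Genes outside this list are not counted here, among them Ifitm1, Ifitm3 and Ly6a, which rose in the stem cell list. Of 16 NF-kappaB and inflammatory genes 5 fell and 1 rose, also when adjusted over the list alone (median -0.81, camera adjusted p = 0.0099, adjusted p = 0.135 with an estimated correlation). Nfkbia, the inhibitor that NF-kappaB itself induces, fell from 176 ± 1.77 to 60.3 ± 6.07 CPM and Traf1 by 2.90 on the log2 scale.

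Most genes of cholesterol synthesis, respiration and glycolysis rose. Of 21 cholesterol biosynthesis genes 19 rose and none fell, also when adjusted over the list alone (median 1.36, camera adjusted p = 5.7e-18, adjusted p = 0.0881 with an estimated correlation), with Fdps at 2.63 ± 0.11, Fdft1 at 1.86 ± 0.11 and Sqle at 1.55 ± 0.11. Of 27 nuclear-encoded genes of oxidative phosphorylation 24 rose and none fell (25 adjusted over the list alone), with a median of 0.75 and a camera adjusted p of 2.3e-11 (adjusted p = 0.0943 with an estimated correlation). With total count scaling 16 rose, with a median of 0.46. Cytochrome c (Cycs) rose from 144 ± 6.43 to 507 ± 76.8 CPM. Of 19 glycolysis genes 14 rose and none fell (15 and 1 adjusted over the list alone), with a median of 0.96 and a camera adjusted p of 2.4e-09 (adjusted p = 0.036 with an estimated correlation). The pyruvate kinase gene, listed as Pkm2, rose from 1159 ± 22.8 to 4333 ± 342 CPM and Pgk1 by 1.51 ± 0.10. Of 14 HIF targets 3 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (median 0.23 but -0.06 with total count scaling, camera adjusted p = 0.387). Nfil3 rose by 2.52 ± 0.20, while Mxi1 and Ndrg1 fell by 1.22 and 0.90 on the log2 scale.

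**Figure D3:**
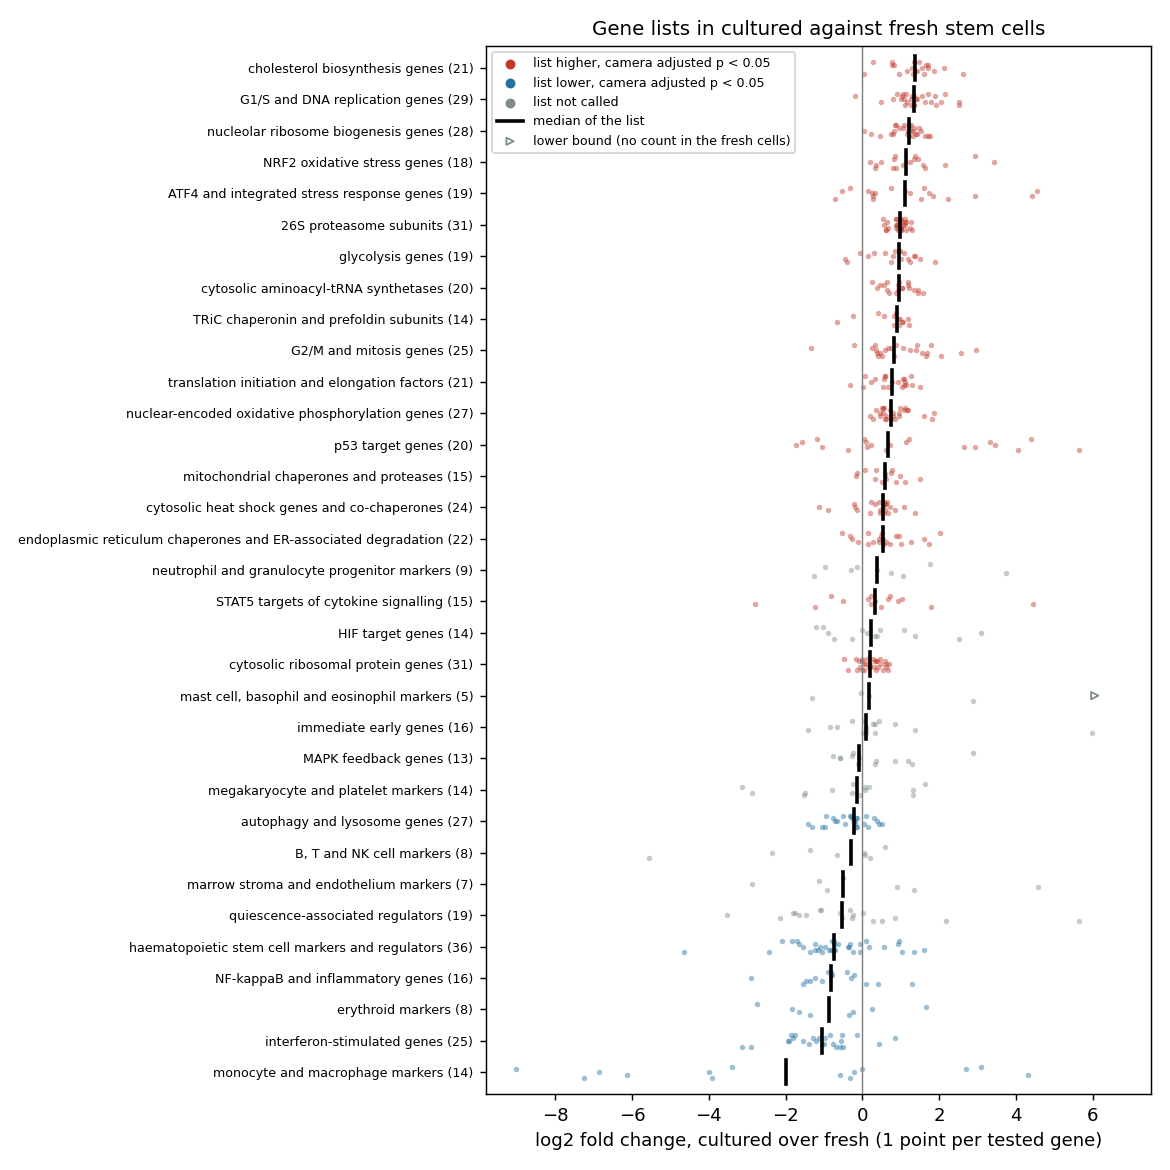
Log2 fold change of each tested gene, cultured over fresh, for the 33 gene lists ordered by their median (black bar), with the number of tested genes in brackets; red and blue lists were called higher or lower by camera and grey lists were not. The proteasome points lie close together around a median of 0.99 and the monocyte and macrophage points lie on both sides of 0; the points of C1qa, C1qb and Vcam1 rest on at most 2 counts in the cultured cells, and the open triangle is the lower bound of Gzmb.

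Markers of other marrow cells were compared between the groups, which shows changes and not which cell types were present. Of 14 tested monocyte and macrophage markers 6 fell and 3 rose, also when adjusted over the list alone (median -1.99, camera adjusted p = 0.0032, adjusted p = 0.220 with an estimated correlation, 0.0752 by limma-voom, lowest of the alternatives 0.000219). The median moved with the libraries and filter used, to -0.26 without fresh library 9, -1.15 without fresh library 7, -3.95 without fresh library 8, -4.08 without cultured library 11, -3.99 with the filter of 50 counts and -0.59 with thinned libraries. Lyz2 fell by 3.93 on the log2 scale and Lyz1 went from 49 ± 3.84 to 3.07 ± 1.26 CPM. The complement gene C1qb went from 704 counts over the 3 fresh libraries to 1 count in culture, a ratio of 771 (95% Clopper-Pearson interval 138 to 30500, counting error only). Vcam1 went from 307 to 2 counts, a ratio of 168 (46.1 to 1390). C1qa and C1qc also fell. Against them, Cd68 rose, as did Csf1r and Cd14. The C1q genes, Vcam1, Csf1r and Cd14 were named after their values were seen. Of 8 tested erythroid markers 3 fell and 1 rose, also when adjusted over the list alone (median -0.87, camera adjusted p = 0.0179, adjusted p = 0.185 with an estimated correlation, 0.0527 with no filter on low counts). The lowest adjusted p of the alternatives for this list, 0.00436, came from fry, which does not compare the list with other genes. The erythroid median was -0.27 with no filter and -1.38 with thinned libraries. Car2, which had 2056 ± 79.5 CPM in fresh cells, fell by 1.38 on the log2 scale, and the transcription factor gene Gata1 fell by 1.83.

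The remaining marker lists were not called. Of 14 megakaryocyte and platelet markers 3 rose and 3 fell (3 and 4 adjusted over the list alone, median -0.15, camera adjusted p = 0.908, with the test's direction upward without cultured library 10 or 12), with Pf4 at 1.63 ± 0.38, F2r at 1.31 ± 0.11 and Gp9 falling by 1.48 on the log2 scale. Of 9 neutrophil and granulocyte progenitor markers 2 rose and none fell, also when adjusted over the list alone (median 0.38, camera adjusted p = 0.380), and Prtn3, the most abundant, did not pass (0.38 ± 0.18, edgeR adjusted p = 0.134). Some untested markers, named after their values were seen, had counts mainly in single libraries. S100a9 had 0, 3 and 82 counts in fresh 7, 8 and 9 and 1, 58 and 6 in cultured 10, 11 and 12. Camp had 0, 4 and 73 in the fresh and 0, 25 and 0 in the cultured libraries. The B cell marker Ms4a1 had 26 counts, all in fresh 9. Of 8 B, T and NK cell markers 3 fell and none rose, also when adjusted over the list alone (median -0.31, mean -1.14, camera adjusted p = 0.230). Cd79b fell by 0.66 on the log2 scale. Klrb1c went from 8.36 ± 4.80 to 0.17 ± 0.19 CPM, near the detection floor in culture. Cd4 went from 4.51 ± 0.76 to 0.87 ± 0.67 CPM, and its fall passed in 11 of 16 alternatives. Of 5 mast cell, basophil and eosinophil markers 1 rose, also when adjusted over the list alone (median 0.16, also with Gzmb at its bound, but -0.13 with total count scaling, camera adjusted p = 0.225). That gene was Gzmb, with no count in the fresh libraries and 10.8 ± 3.07 CPM in the cultured ones, at least 66.2-fold higher against the mean of the fresh libraries' floors of 3 counts (0.163 CPM). Of 7 marrow stroma and endothelium markers 2 rose and none fell (2 and 3 adjusted over the list alone), with Pecam1 at 1.35 ± 0.12. The median of this list was -0.51 while its mean of 0.19 and the direction of the camera test were upward (adjusted p = 0.591).

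The libraries differed in composition and in how expression varied with transcript length. The 100 most abundant genes of each library took 18.4 ± 0.20% of the counts in fresh and 20.7 ± 0.14% in cultured cells (SD, n = 3 per group, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Thinned to the smallest total, the fresh libraries held 12171 ± 47.3 genes with at least 10 counts and the cultured libraries 11622 ± 206 (n = 3 per group, exact permutation p = 0.1). The share of mitochondrial transcripts could not be computed, because no mitochondrially encoded gene is listed. Across 12296 genes with a known transcript length, which are not independent replicates, the log2 fold change fell with length (Spearman's rho -0.217). Among the 2460 genes with the shortest transcripts 33.1% rose and 10.4% fell, and among the 2459 with the longest 9.15% rose and 21.5% fell. With offsets for GC content and length, chosen after the data were seen, the median of the proteasome list was 0.76, of the oxidative phosphorylation list 0.57, of the replication list 1.33, of the stem cell list -0.62 and of the interferon list -1.13, all still called by camera at the preset correlation. With an estimated correlation and no offsets, only the proteasome list of these kept its call. The ribosomal protein list lost its call under these offsets and its median turned to -0.08 (adjusted p = 0.378).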

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

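Offsets for GC content and length, and thinning, were chosen after the data were seen. No paired analysis was run, because the groups share no library number and no label pairs their libraries. The labels do not say whether libraries were handled together in order, and the second principal component ran in the same order in both groups (-34.8, -13.1 and 46.0 in fresh 7, 8 and 9, -20.3, -15.3 and 37.6 in cultured 10, 11 and 12), so a shared batch was neither established nor tested. No call of a gene turned to the opposite direction in any of the 16 settings. Total count scaling gave 1620 rises and 3621 falls, 168 and 547 beyond 2-fold, and it moved the median of all genes by -0.29. Upper-quartile factors gave 208 rises beyond 2-fold, and limma-voom 150 rises and 101 falls beyond 2-fold. Leaving out each library gave 2069 to 2445 rises and 1542 to 1961 falls, with 174 to 308 and 170 to 256 beyond 2-fold, from fewer samples; the counts beyond 2-fold moved by over 1.5 times without fresh 7, 8 or 9 and without cultured 10 or 11. The difference in the share of the 100 most abundant genes ranged from 2.13 to 2.31 percentage points.

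With an estimated correlation 21 called lists had an adjusted p over 0.05: heat shock 0.189, TRiC 0.08808, mitochondrial chaperones 0.08984, endoplasmic reticulum 0.3231, ATF4 0.05479, autophagy 0.1221, ribosome biogenesis 0.05479, ribosomal proteins 0.6211, tRNA synthetases 0.1241, G1/S 0.2202, G2/M 0.6211, stem cell 0.08808, STAT5 0.1388, p53 0.1957, NRF2 0.08808, interferon 0.189, NF-kappaB 0.1348, oxidative phosphorylation 0.09433, cholesterol 0.08808, erythroid 0.1852, and monocyte and macrophage 0.2202. Fry, which asks another question, did not call ribosomal proteins (0.08328) or G2/M (0.1104) and called quiescence (0.04751), immediate early (0.03619), MAPK (0.01746), HIF (0.01243), lymphoid (0.0001218), mast cell (0.00753) and stroma (0.04751), and gave the uncalled megakaryocyte list the upward direction (0.8303).

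The ribosomal protein list lost its call with total counts (0.4994), upper-quartile factors (0.1926), the filter of 50 counts (0.1006) and, turning downward, with GC and length offsets (0.3783), and ranged from 0.00824 to 0.3049 over the libraries left out. Erythroid markers had 0.05265 with no filter, and with limma-voom STAT5 targets had 0.07727 and monocyte markers 0.07524. The G2/M list ranged from 8.5e-05 to 0.07618 over the libraries left out, and the megakaryocyte list from 0.616 to 0.981, upward without cultured 10 (0.8331) or 12 (0.9032). Mki67, which never passed, ranged from -0.17 without cultured 10 to 0.79 without cultured 12. The cause was not tested for these or for the lists above. The ribosomal protein list had no value without its own genes, and the mast cell list none with the filter of 50 counts or thinned libraries, where too few members were tested. Beyond this, the lists kept their side of the threshold, and with libraries thinned to equal depth all 143 named genes with a value kept direction and side.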

Other observations

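The lists of this paragraph were chosen after values had been seen, and each median keeps the TMM scale. Most tubulin genes rose. Of 13 tested, 10 rose and none fell (median 1.43, camera adjusted p = 2.3e-09 over 6 added lists, unadjusted p = 0.00816 with an estimated correlation). Tubb5 reached 3705 ± 374 CPM in cultured against 1366 ± 324 CPM in fresh cells. Of 76 genes for mitochondrial ribosomal proteins 56 rose and none fell (median 0.80, camera adjusted p = 5.3e-15, unadjusted p = 0.0415 with an estimated correlation). Of 5 genes of the immunoproteasome and its activator 4 rose (median 0.79, camera adjusted p = 9.8e-05, unadjusted p = 0.0315 with an estimated correlation), with Psme2 at 1.43 ± 0.12 and Psmb8 at 0.77 ± 0.09, and Psmb9 did not pass (0.21 ± 0.13, edgeR adjusted p = 0.220).

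The lists of this paragraph were also chosen after values had been seen. Of 326 zinc finger genes with a Zfp symbol 118 fell and 16 rose (median -0.66, camera adjusted p = 4.5e-07, unadjusted p = 0.00387 with an estimated correlation). Of 5 nuclear long non-coding RNAs 4 fell and none rose (median -2.27, camera adjusted p = 0.000679, unadjusted p = 0.0324 with an estimated correlation). Malat1 went from 1148 ± 272 to 203 ± 39.4 CPM, and Neat1, Xist and Tug1 fell by 2.65, 1.35 and 1.06 on the log2 scale. With offsets for GC content and length the medians were -0.58 for the zinc finger genes, -1.87 for the long non-coding RNAs, 1.34 for tubulins and 0.63 for mitochondrial ribosomal proteins. The cytokine receptor subunit genes Csf2rb and Csf2rb2 rose by 2.88 ± 0.27 and 3.42 ± 0.29.

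In what follows, the tests with GC and length offsets, total count scaling and thinning on the proteasome list, the matched random lists and the count of macrophage markers by direction were chosen after the result was seen. The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits as large as the real one cannot be under 0.05. The real split, the 1 counted, called 4689 genes by edgeR and 581 beyond 2-fold, and the highest of the others called 0 and 0, with 82 to 267 genes at an unadjusted p under 0.05 against 5820. For gene lists by camera the real split called 24 and the highest other 17. Each other split mixes the groups 2 to 1, so a difference between the groups widens the spread within each arm. Few gene calls in those splits were therefore largely fixed in advance, and 0 against 4689 is no separate evidence.

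The proteasome, ribosome biogenesis and replication lists were each called higher by camera, but with an estimated correlation only the proteasome list kept its call (adjusted p = 0.036, against 0.0548 and 0.220). The median of the proteasome list was 0.99, and it was 0.758 with GC and length offsets, 0.694 with total count scaling and 0.959 with libraries thinned to equal depth, each called by camera (highest adjusted p of the 3, 4.5e-16). The value with offsets argues only against a GC or length bias that is alike at all expression levels as the whole cause of that list's rise. The offsets do not take expression level into account, and the proteasome genes were not compared with genes matched on it. Total count scaling shifts all genes nearly alike (median -0.29), and thinning leaves expected fold changes unchanged. Both outcomes were therefore largely fixed in advance. They show only that the rise exceeded the shift between the scalings and stood at equal depth. A hypothesis is that cells leaving rest in the cytokine medium raise the machinery for making and degrading proteins. No test here separates this from any other effect of 18 h outside the marrow. Some genes did not go with it. Among autophagy and lysosome genes 8 fell and 3 rose, ribosomal protein genes moved little, and the cell cycle inhibitor gene Cdkn1a rose.

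The log2 fold change fell weakly with transcript length (Spearman's rho -0.217 across 12296 genes). Deviations from the gene mean correlated with length at rho 0.203, 0.140 and 0.163 in the fresh and -0.139, -0.188 and -0.188 in the cultured libraries, so the trend lies between the groups. The 31 ribosomal protein genes had a median of 0.205, at percentile 0 of 10000 random lists matched on length and expression (median 0.675, central 95% from 0.467 to 0.883). They thus rose less than other genes of their length and expression. The random lists drew genes independently, while ribosomal protein genes move together (estimated correlation 0.551), so the spread of the random lists is too narrow. A single such list cannot decide whether RNA quality or library length bias set the trend in the other genes. Among 11677 genes in no list rho was -0.214, so the trend stood without the 619 genes of the lists. The lists hold so few of the 12296 genes that this outcome was nearly fixed in advance. A length bias or a true shift toward short messages may each remain, and no test here separates them.

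Monocyte and macrophage markers moved apart. In the minority direction, 3 called markers rose while 6 fell. This count restates the pattern and is no separate test. It argues only against a change in the share of monocytes or macrophages among the cells, shared by all markers, as the whole cause. For Lyz2 and the C1q genes, loss of 1 contaminating cell type in the fresh cells could account for the fall. The ratio to Lyz2 counts differed between the fresh libraries 2.5-fold for C1qa, between the bounds of 1.5 and 3 set in advance, and (chosen after) 1.61-fold for C1qb and 1.75-fold for C1qc, highest in library 9 where C1qa was lowest, so this cannot be told apart from a fall in the stem cells themselves. The labels give no sort gate, and a change in the cells that raised Cd68, Csf1r and Cd14 also stays open.

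A hypothesis from the fall of Pik3ip1, Sesn1, Txnip and Bcl6, which are among the targets of FOXO transcription factors, was lower FOXO activity in culture. These genes were picked because they fell, so they are no evidence for it. Sesn1 also stands in the p53 list, and Cdkn1a, in the quiescence list with Txnip, rose. The hypothesis was tested on 12 FOXO targets whose values had not been looked at. Their median was -0.651, 4 fell and 1 rose, and camera gave p = 0.0942 (0.153 with an estimated correlation), so the test left the hypothesis undecided. Insr, Fbxo32, Rictor and Cat fell by 1.69, 1.43, 1.41 and 0.66 on the log2 scale, and Sod2 rose by 1.04 ± 0.11.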
